A study of Homo sapiens with 9 samples.

How the data were processed

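RNA from PC3 cells was hybridised to 9 Illumina bead arrays, 3 per group. Per the labels' protocols, the cells were grown in DMEM with fetal bovine serum, the ligand GW501516 was given from a DMSO stock to a final 0.1 µM, and biotin-labelled RNA was made with an Epicentre kit. The groups were taken from the sample labels, and replicate numbers 4, 5 and 6 from the sample titles. The titles of the control arrays and of the arrays labelled PPARD carry a V where those of the ligand-treated arrays carry GW, and the control titles also carry the word Babe. The control group's label names a vehicle control, but no label explains the V in the titles of the arrays labelled PPARD, or the word Babe. Whether the arrays labelled PPARD received the solvent, and what construct the control cells carried, is therefore not stated in the sources used here.

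The authors deposited a table of raw probe intensity values with a detection p-value beside each, for 47323 probes on the 9 arrays. These intensity values are not normalized, as deposited, and the software that made them is not given in the sources used here. Detection p-values are as deposited by the authors, and their steps imply 770 negative control probes per array. Each p-value column was taken as belonging to the intensity column before it, which the values bear out, since the rank correlation with the own array was stronger on each array than that with any other. The authors also deposited processed log2 values for 21000 probes. Tested on the values, these are the probes with a detection p below 0.01 on at least 1 array, and the deposited log2 values equal quantile-normalized log2 raw intensities without background correction (largest difference 5.15e-14). Each column of the processed values matched its own array best (9 of 9) and had a median of 7.05. They are on an absolute log2 scale, neither centred on genes nor expressed as ratios.

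For the main values the raw intensities were corrected with the neqc function of limma 3.58.1 in R 4.3.3, which fits a normal plus exponential background with negative control statistics inferred from the detection p-values, applies quantile normalization, adds an offset of 16 and takes log2. The offset understates the change of dim genes. Probes with a detection p below 0.01 on at least 3 of 9 arrays were kept, 17428 in all. Gene names came from the platform's annotation of the processed probes, of which 16078 had 1 symbol, 1 had several and 4921 had none. Through their gene identifiers 16065 matched the RefSeq gene table of the assembly GRCh38.p14, and 0 symbols changed. Of the 17428 probes 14115 had 1 symbol and 3313 were unnamed here. The probe with the highest mean over the 9 arrays stood for its gene, which gave 10652 genes. Of these, 2809 had several probes, and their probes were called in opposite directions for 2, 0 and 4 genes in the 3 contrasts (PPARD against control, ligand-treated against PPARD, ligand-treated against control). No coordinates are given, since no genome build is named for the values.

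A linear model with the 3 groups was fitted to all 9 arrays with lmFit, which leaves 6 residual degrees of freedom per gene, and moderated with eBayes. The 3 contrasts were each adjusted by the Benjamini-Hochberg method, and genes with an adjusted p below 0.05 are called changed. At an unadjusted p below 0.05 the contrasts held 3302, 2363 and 3883 genes. Where a probe was not detected on any array of a group, the other group is given as at least N-fold higher or lower: the bright group's mean was set against the dim group's mean of, per array, the higher of the lowest signal among detected probes and the probe's own signal.

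Before the data were examined, 18 gene lists were fixed from general knowledge of PPAR biology, lipid metabolism, mucosal and prostate markers, stress responses and other cell types, together with the design, the alternatives and the rule for named genes. The rule names PPARD and the trefoil factors, the 10 largest rises and falls per contrast among called genes with a full symbol, and per list up to 4 measured members with the largest change, or any called member of a list that camera called. MKI67, TOP2A and CCNB1 of the proliferation list were named after their values were seen. The 16 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01 between genes, adjusted over 48 tests, and again with an estimated correlation. The second setting also uses far fewer degrees of freedom, namely the 6 residual ones, which raises p-values by itself. Of the 48 tests 18 passed, and 5 with an estimated correlation: PPAR target genes and cholesterol synthesis genes in both contrasts with the ligand, and hypoxia and glycolysis genes in ligand-treated against control arrays. In 7 tests the list's median, mean and camera direction differed in sign, and 0 of these passed. They were fatty acid oxidation, fatty acid synthesis, NF-kB targets and NRF2 genes on arrays labelled PPARD against control, proliferation and mesenchymal genes with the ligand against PPARD, and ATF4 genes with the ligand against control.

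The fit was tested on simulated data for 10652 genes with the real means and spreads, in which 200 genes were changed by known folds, 20 times per contrast. For PPARD against control 26.6% of genes changed 1.25-fold were recovered, 92.5% at 1.5-fold and 99.8% at 2-fold, with 5.94% false calls. For ligand-treated against PPARD the shares were 23.8%, 92.9% and 99.7% with 4.87% false calls, and for ligand-treated against control 27.6%, 92.4% and 99.8% with 5.59%. In all of them 0 genes were called in the wrong direction. Besides the 200 genes a small list was shifted as a whole. On the arrays a larger share of genes was called than was changed here, namely 16.4%, 9.07% and 23.0% in the 3 contrasts. The Benjamini-Hochberg threshold depends on that share, so recovery of small changes on the arrays may differ. Figures were drawn with matplotlib 3.10.9.

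Alternatives were the replicate number as a block, scaling to the 75th percentile, no background correction, the authors' processed values, no detection filter, detection on all 9 arrays, every probe on its own, an intensity trend with a robust prior, fits of only the 2 groups compared, other probes of a named gene, an estimated correlation in camera, and leaving out each array in turn. The number of detected probes per array lay between 16028 and 17280, and the 3 arrays per group limit the precision.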

Results

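Gene expression was measured on 9 Illumina bead arrays in PC3, an established cell line derived from a metastatic human prostate cancer that grows without androgen. The arrays fall into 3 groups of 3. The control group carries the label of a vehicle control, the second group is labelled as overexpressing PPARD, and the third is labelled as overexpressing PPARD and treated with GW501516 at 0.1 µM. PPARD encodes PPARδ, a nuclear receptor that binds fatty acids and regulates genes of lipid metabolism, and GW501516 is a synthetic agonist of it. The design asks which genes change when the receptor is raised without added ligand, and which change again when the ligand is added. The series title places the trefoil factors, small secreted peptides of mucosal surfaces, at the centre of the first question. No group received GW501516 without the PPARD construct, so an effect of the ligand through the endogenous receptor is part of the ligand contrast.

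Between 16028 and 17280 of 47323 probes per array were detected, which is 33.9% to 36.5%, and the median raw signal lay between 83.1 and 84.9. After normalization, arrays of 1 group correlated at 0.993 to 0.995 over the 10652 genes tested, and arrays of different groups at 0.982 to 0.989. All 9 arrays correlated best with an array of their own group. The first principal component held 39.6% of the variance and the second 24.9%. Values below are log2 fold changes ± SE from a fit over 3 arrays per group, and genes are said to rise or fall when the adjusted p from limma was below 0.05. The number of arrays limits the precision. The labels do not say whether the arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

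The introduced gene was examined first. The brighter of 2 probes named PPARD gave a log2 level of 6.21 ± 0.09 (SD, n = 3) on control arrays and 5.90 ± 0.14 (SD, n = 3) on arrays labelled PPARD. The difference was -0.31 ± 0.10 with an adjusted p of 0.0649, so the probe did not rise on the arrays labelled PPARD. The other probe was detected on 2 of 9 arrays, 0 of them labelled PPARD, and was not tested. Its raw signal lay between 81.8 and 90.6 on control arrays and between 83.5 and 88.3 on arrays labelled PPARD. The brighter probe differed by 0.35 ± 0.10 between arrays with and without GW501516 (adjusted p = 0.0618), and by 0.04 ± 0.10 between ligand-treated and control arrays (adjusted p = 0.834). Both near-threshold p-values moved below 0.05 when ligand-treated replicate 4 was left out, to 0.0445 and 0.0278, and under some other settings. Over all settings they ranged up to 0.195 and 0.202. Whether either probe lies inside the introduced sequence is not given in the sources used here, and a probe outside it checks nothing. The PPARD groups are therefore named by their labels throughout.

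All 3 trefoil factors were lower on the arrays labelled PPARD than on control arrays. TFF2 fell by 2.77 ± 0.08 on the log2 scale, a 6.82-fold difference (adjusted p = 1.35e-09). TFF3 fell by 2.38 ± 0.08, or 5.21-fold (adjusted p = 7.74e-09), and TFF1 fell by 1.54 ± 0.07, or 2.90-fold (adjusted p = 1.89e-07). For each of the 3 genes the highest array labelled PPARD lay below the lowest control array. The 3 genes also fell when adjusted over the list alone. The study names this family in its title and may have chosen it on these samples, so the count is not independent evidence of the direction.

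**Figure D1:**
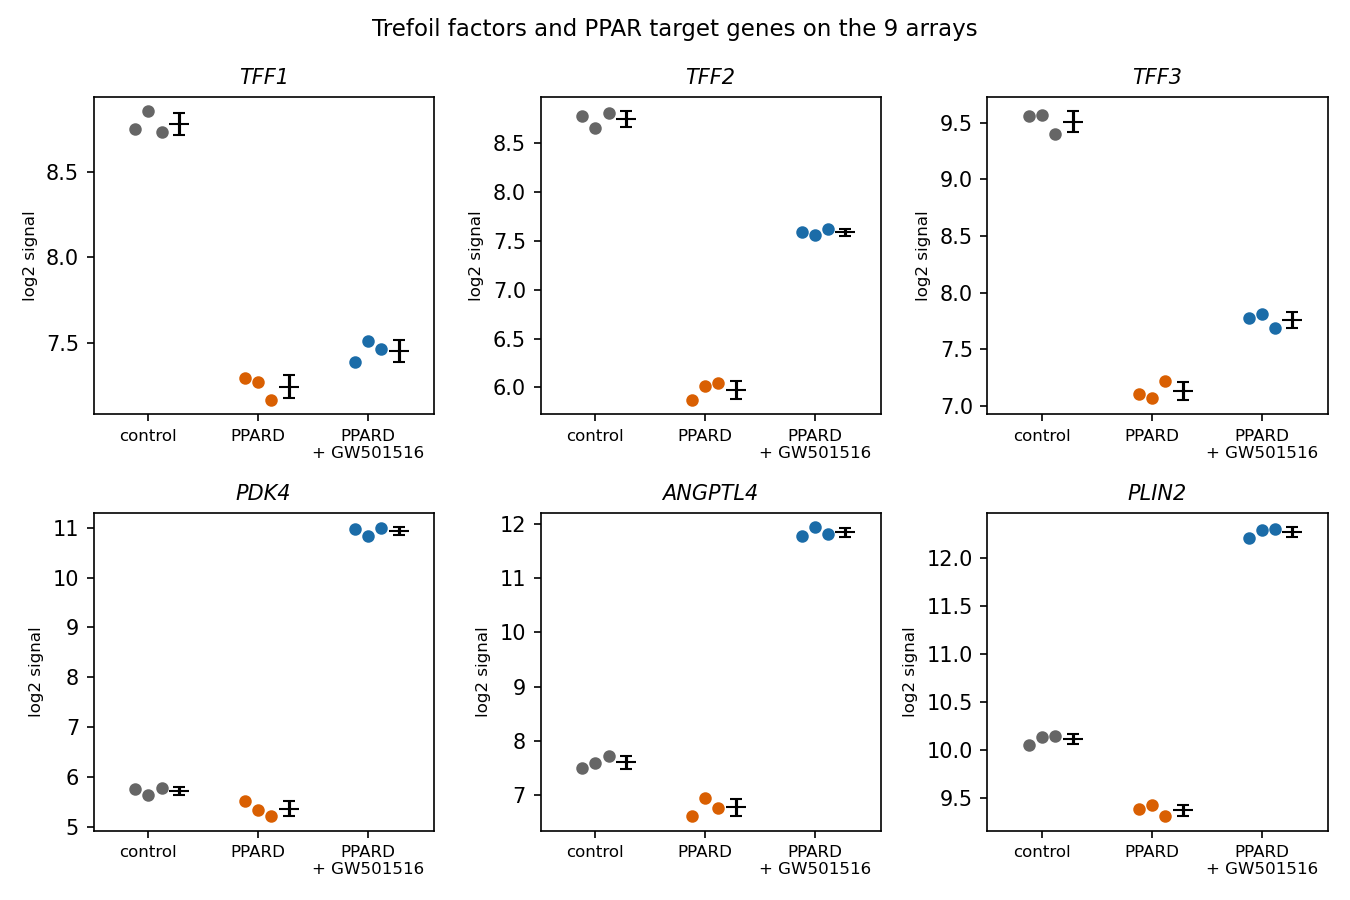
Normalized log2 signal of TFF1, TFF2, TFF3, PDK4, ANGPTL4 and PLIN2 on the 9 arrays, by group. Each point is 1 array and the black bar beside it gives the group mean ± SD (n = 3), each panel having its own axis. TFF2 fell from a mean of 8.75 on control arrays to 5.98 on arrays labelled PPARD and lay at 7.59 with GW501516, while PDK4 lay at 5.72, 5.36 and 10.9.

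Across all genes, 1746 of 10652 (16.4%) changed between arrays labelled PPARD and control arrays, with 1023 higher and 723 lower. Of these, 49 rose and 23 fell by 2-fold or more. The largest rise was that of MSMP, a secreted prostate microseminoprotein, at 2.95 ± 0.07 (7.72-fold, adjusted p = 1.35e-09). EPB41L3, a membrane skeleton protein, rose by 2.34 ± 0.10 and IGFBP2, which binds insulin-like growth factors, by 2.07 ± 0.11. LINC00261 rose by 1.89 and the collagen gene COL1A2 by 1.82. EPB41L3 and LINC00261 were each detected on 2 of 3 control arrays. RRAGD and MAP1LC3A, a Rag GTPase and an autophagosome protein, each rose by 1.76. The interferon-induced gene IFI44, the chemokine gene CXCL8 and the peptide hormone gene UTS2 rose by 1.70, 1.68 and 1.67. Beside the trefoil factors, the largest falls were those of PASD1, a cancer-testis antigen (-2.61 ± 0.07), and TUB, which was not above background on any array labelled PPARD and was at least 3.90-fold lower there. KLK6, a kallikrein protease, fell by 1.73 and was detected on 1 array labelled PPARD. IL13RA2, CCL26, MAGEA10 and TNFAIP6 fell by 1.69, 1.62, 1.54 and 1.45. Leaving out PPARD replicate 4, 5 or 6 lowered the count from 1746 to 1177, 1171 and 1128, in that order.

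Interferon response genes rose in this contrast. Of 33 measured, 22 rose and 1 fell (23 and 3 adjusted over the list alone). IFI44 rose by 1.70 ± 0.10, IFI27 by 1.42 ± 0.28, IFI44L by 1.35 ± 0.13 and IFIT2 by 1.28 ± 0.08. IFI44L had a second probe, which gave -0.00. The member that fell was OAS1, a sensor of double-stranded RNA, at -0.56. The list was higher than other genes with camera at its preset correlation (adjusted p = 2.46e-10). With an estimated correlation, which was 0.43 for this list, the adjusted p = 0.180. IFITM1, IFITM2 and IFITM3 are near-identical genes whose probes may not separate them.

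Proliferation genes fell: 14 of 44 measured were lower and 0 higher (18 and 0 adjusted over the list alone). The replication licensing factor CDT1 fell by 0.46 ± 0.08, the checkpoint kinase CHEK1 by 0.45 ± 0.10 and the sliding clamp PCNA by 0.44 ± 0.11. E2F1 was not above background on any array labelled PPARD and was at least 1.21-fold lower there than on control arrays, of which 2 of 3 detected it. MKI67, TOP2A and CCNB1 gave -0.08, -0.04 and -0.00 and were not called. The list was lower with camera (adjusted p = 9.13e-06; adjusted p = 0.0635 with an estimated correlation).

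PPAR target genes were lower on arrays labelled PPARD than on control arrays, and the labels name no added ligand for either. Of 21 measured, 8 fell and 1 rose (9 and 1 adjusted over the list alone). ANGPTL4, an inhibitor of lipoprotein lipase, fell by 0.83 ± 0.10 and the mitochondrial carnitine carrier SLC25A20 by 0.77 ± 0.09. The lipid droplet protein PLIN2 fell by 0.74 ± 0.07 and PDK4, an inhibitory kinase of pyruvate dehydrogenase, by 0.36. CPT1A fell by 0.61 ± 0.09 with its brightest probe, but its other probes gave 0.03 and 0.07. TXNIP rose by 0.40. The list was lower with camera (adjusted p = 8.80e-04; adjusted p = 0.0808 with an estimated correlation).

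Hypoxia and glycolysis genes were higher: 10 of 33 rose and 1 fell (13 and 2 adjusted over the list alone). PFKFB4 rose by 0.61 ± 0.08 and ALDOC, ANKRD37 and BNIP3L by 0.47, 0.47 and 0.46, while the carbonic anhydrase gene CA12 fell. The camera test gave an adjusted p of 0.00167 and, with an estimated correlation, an adjusted p of 0.108. Of 17 epithelial genes, 6 rose and 2 fell, the same counts adjusted over the list alone. ITGB4, KRT8 and CLDN3 rose by 0.55, 0.53 and 0.50, and CLDN7, detected on 2 of 3 arrays labelled PPARD, fell by 0.60. The list's adjusted p was 0.0236, and adjusted p = 0.162 with an estimated correlation. Without control replicate 4 the epithelial call was lost (adjusted p = 0.0550).

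The other lists did not pass camera in this contrast. Mesenchymal and TGF-beta genes had 4 rises and 2 falls among 27 (adjusted p = 0.0646), with COL1A2, LUM and SPARC up by 1.82, 1.46 and 0.97. LUM and SPARC were each detected on 1 of 3 control arrays, so the sizes of their rises are uncertain. Cholesterol synthesis genes had 3 rises and 0 falls among 19 (adjusted p = 0.0646; 5 and 0 adjusted over the list alone), led by TM7SF2 at 1.00 ± 0.09. Nuclear receptors and coregulators had 1 and 1 among 21 (0.0806), ATF4 and unfolded protein response genes 4 and 6 among 39 (0.159), and androgen receptor and luminal prostate markers 1 and 1 among 10 (0.532). NRF2 and metallothionein genes had 5 and 4 among 22 (0.592), where MT1F rose by 1.24 ± 0.07, and mucosal secretory genes 4 and 4 among 14 (0.732), where FOXA2 rose by 1.41 and CEACAM6 fell by 1.36. Fatty acid oxidation genes had 3 and 1 among 29, fatty acid synthesis genes 1 and 1 among 18, NF-kB targets 2 and 2 among 15, and oxidative phosphorylation genes 0 and 1 among 43, each with an adjusted p of 0.911. The cholesterol list passed without background correction (adjusted p = 0.0349) and with the authors' processed values (adjusted p = 0.0375), and the mesenchymal list without control replicate 5 or control replicate 6 (adjusted p = 0.0398 and 0.0481). Metallothionein genes and AKR1C genes are families of close copies whose probes may not separate them. Among 4 measured blood and neuroendocrine markers, too few for a list test, SYT1 rose by 0.31 and CD68, INSM1 and CD14 gave -0.13, 0.05 and -0.01, INSM1 being detected on 1 of 3 control arrays.

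**Figure D2:**
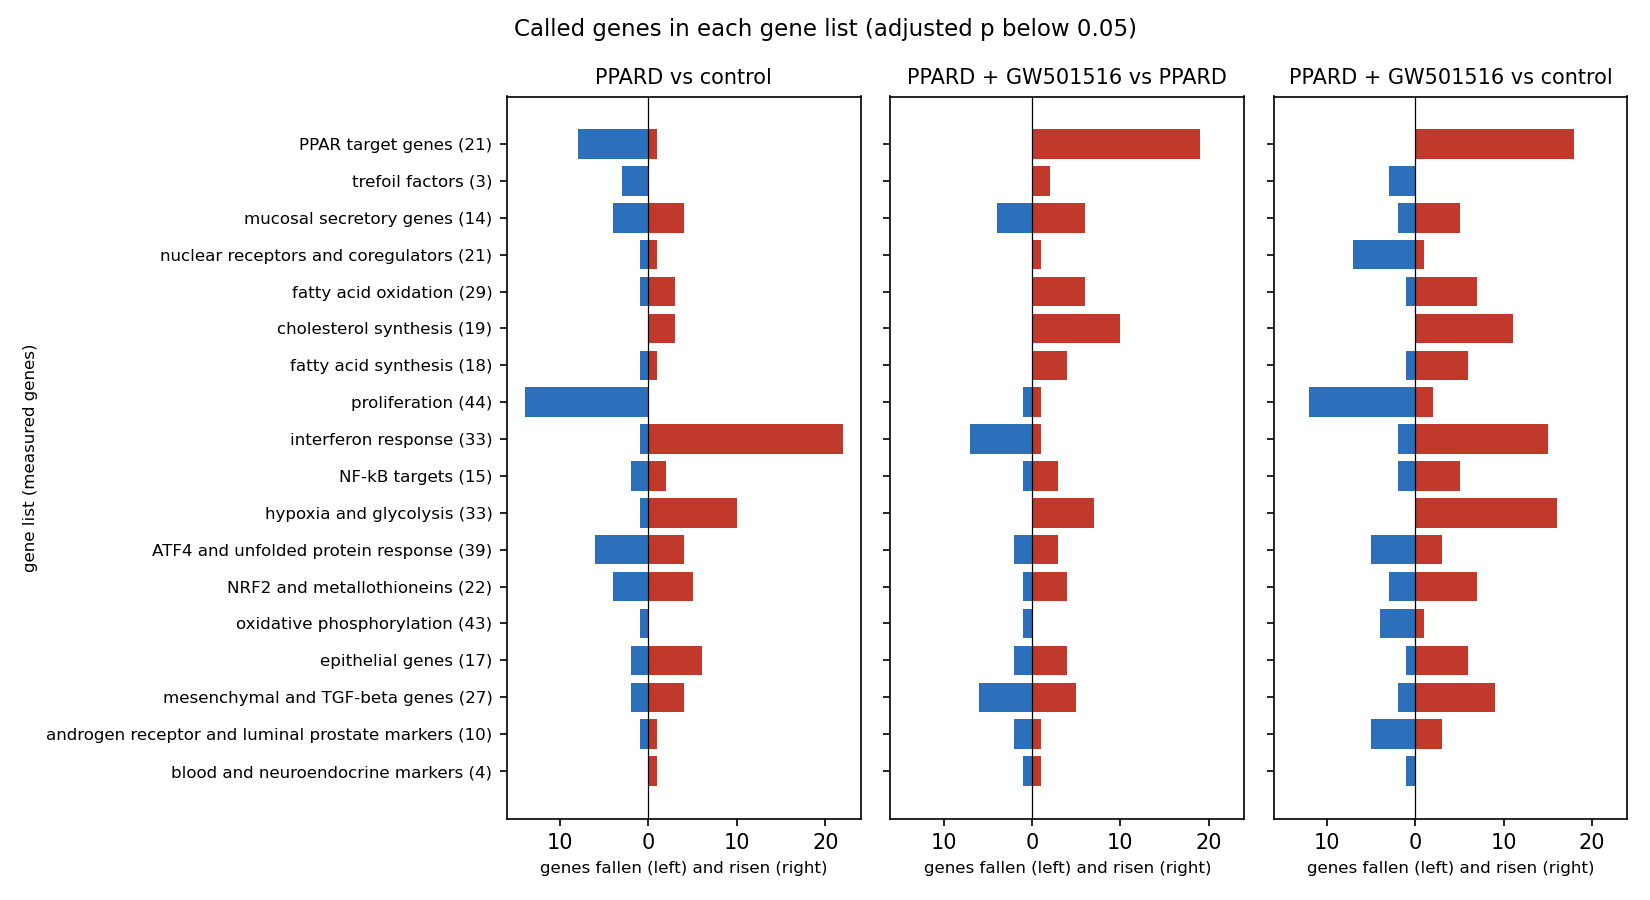
Number of genes in each list that fell (bars to the left of 0) or rose (bars to the right of 0) in the 3 contrasts at an adjusted p below 0.05, with the number measured in parentheses. PPAR target genes show 8 falls and 1 rise on arrays labelled PPARD against control and 19 rises and 0 falls with GW501516 against PPARD.

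Adding GW501516 to the PPARD-labelled cells raised the PPAR target genes. Of 21 measured, 19 rose and 0 fell, the same counts adjusted over the list alone. PDK4 rose by 5.57 ± 0.09, a 47.4-fold change (adjusted p = 8.13e-12), ANGPTL4 by 5.06 ± 0.10, or 33.3-fold (adjusted p = 2.89e-11), and PLIN2 by 2.89 ± 0.07, or 7.42-fold (adjusted p = 3.12e-10). SLC25A20 rose by 1.38, the very low density lipoprotein receptor gene VLDLR by 1.20 and the acyl-CoA dehydrogenase gene ACADVL by 1.18. CPT1A rose by 1.56 ± 0.09 with its brightest probe, and another of its probes gave -0.09. The list was higher with camera (adjusted p = 3.59e-33; adjusted p = 0.00125 with an estimated correlation).

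In this contrast 966 genes (9.07%) changed, 516 up and 450 down, of which 47 rose and 28 fell by 2-fold or more. After the 3 PPAR targets above, the largest rises were those of LRRC31 at 2.19 ± 0.11, the growth factor gene BMP6 at 2.00 ± 0.08, the carboxypeptidase gene CPA4 at 1.94 ± 0.08 and the neurotensin gene NTS at 1.93 ± 0.09. PTGER2, a prostaglandin E2 receptor, EPAS1, which encodes HIF-2α, and the receptor tyrosine kinase gene TYRO3 rose by 1.85, 1.84 and 1.66. The largest falls were those of the collagenase gene MMP13 (-2.13 ± 0.10), MSMP (-2.00 ± 0.07), CADPS2 (-1.66 ± 0.09) and TCN1 (-1.61 ± 0.07). PHACTR3, SPRY4, MMP1, LINC00261, DACH1 and POU3F2 fell by 1.57, 1.51, 1.45, 1.45, 1.39 and 1.32. LRRC31 was detected on 1 of 3 arrays labelled PPARD and MMP13 on 1 of 3 ligand-treated arrays, so the sizes and ranks of these changes are uncertain. Without PPARD replicate 4, 5 or 6 the count was 698, 745 and 635, in that order.

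Of the trefoil factors, TFF2 rose by 1.61 ± 0.08 with the ligand, or 3.06-fold (adjusted p = 1.86e-07), and TFF3 by 0.63 ± 0.08, or 1.54-fold (adjusted p = 3.51e-04). TFF1 differed by 0.21 ± 0.07 (adjusted p = 0.113), which passed only when adjusted over the list alone. On ligand-treated arrays all 3 stayed below control, with TFF3 at -1.75 ± 0.08, TFF1 at -1.33 ± 0.07 and TFF2 at -1.16 ± 0.08. The adjusted p-values of these differences were 1.09e-07, 5.37e-07 and 1.77e-06. These results kept their calls under every setting run.

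Cholesterol synthesis genes rose with the ligand: 10 of 19 were higher and 0 lower (14 and 0 adjusted over the list alone). The mevalonate decarboxylase gene MVD rose by 0.49 ± 0.08, CYP51A1 by 0.42 ± 0.11, and INSIG1 and IDI1 by 0.39 each. The camera test gave an adjusted p of 1.16e-07 and, with an estimated correlation, an adjusted p of 0.0101. Hypoxia and glycolysis genes had 7 rises and 0 falls among 33, also adjusted over the list alone. The vasodilator gene ADM rose by 0.67 ± 0.08, P4HA2 by 0.53, NDRG1 by 0.46 and ENO2 by 0.41. Their adjusted p was 2.07e-05, and adjusted p = 0.0572 with an estimated correlation. Fatty acid synthesis genes had 4 rises and 0 falls among 18 (5 and 0 adjusted over the list alone), with ACACB and AGPAT2 up by 0.39 and 0.37. The adjusted p was 0.00424, and adjusted p = 0.167 with an estimated correlation. ACACB makes the malonyl-CoA that inhibits fatty acid entry into mitochondria, a role apart from the synthesis of fatty acids. Fatty acid oxidation genes outside the PPAR target list had 6 rises and 0 falls among 29 (7 and 1 adjusted over the list alone), with HADHB, PEX11A and ETFA up by 0.57, 0.55 and 0.52. ETFA had fallen by 0.55 ± 0.09 on arrays labelled PPARD against control, so its rise did no more than regain that fall. The list's adjusted p was 0.0316, and adjusted p = 0.154 with an estimated correlation.

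Interferon response genes moved down with the ligand, with 7 falls and 1 rise among 33 (9 and 1 adjusted over the list alone). IFIT2 fell by 1.01 ± 0.08, IFIT1 by 0.84 ± 0.12, IFI44 by 0.63 ± 0.10 and HERC5 by 0.60 ± 0.10, and OAS1 rose by 0.37. The adjusted p was 0.0282 with camera, and adjusted p = 0.609 with an estimated correlation. The call was lost without ligand-treated replicate 4, PPARD replicate 5 or ligand-treated replicate 6 (adjusted p = 0.239, 0.161 and 0.0664). The fatty acid oxidation call was lost without ligand-treated replicate 4, ligand-treated replicate 5 or PPARD replicate 6 (adjusted p = 0.0684, 0.0580 and 0.0647).

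Proliferation genes showed 1 rise and 1 fall among 44 with the ligand (adjusted p = 0.592). E2F1 rose, being at least 1.33-fold higher, and BIRC5 fell by 0.27. Of 17 epithelial genes 4 rose and 2 fell (adjusted p = 0.0591; 7 and 3 adjusted over the list alone). ITGB4 rose by 1.28 ± 0.09 and CDH1, which encodes E-cadherin, by 0.54 ± 0.12, while KRT8 and CLDN3 fell by 0.66 and 0.57. NRF2 and metallothionein genes had 4 rises and 1 fall among 22 (0.0591), with ABCC3, HMOX1 and AKR1C2 up by 1.21, 0.94 and 0.83 and MT1F down (-0.79). Oxidative phosphorylation genes had 0 and 1 among 43 (0.0951), the fall being that of ATP5MC1 at -0.27, whose other probe gave 0.06. Mucosal secretory genes had 6 and 4 among 14 (0.142), with CEACAM6 and SLPI up by 1.66 and 0.81 and the mucus protein gene FCGBP down (-1.31). ATF4 and unfolded protein response genes had 3 and 2 among 39 (0.157), with GDF15 up by 1.15, and NF-kB targets 3 and 1 among 15 (0.225), with IL1B up by 1.34 and CXCL8 down (-1.21). Androgen receptor and luminal prostate markers had 1 and 2 among 10 (0.373), with HOXB13 at -0.92 and SLC45A3 at 0.64. Mesenchymal and TGF-beta genes had 5 and 6 among 27 (0.624), with THBS1 and COL6A3 up by 1.42 and 1.36 and CCN2 down (-1.16). Nuclear receptors and coregulators had 1 and 0 among 21 (0.732), the rise being that of ESRRA at 0.35. Some of these calls depended on the setting. The NRF2 list passed as higher under all 3 other value scales (adjusted p = 0.0229 to 0.0362) and without PPARD replicate 4 or ligand-treated replicate 5 (adjusted p = 0.0400 and 0.0499). Without background correction and with the authors' processed values the epithelial list passed as higher (adjusted p = 0.0451 and 0.0460) and the oxidative phosphorylation list as lower (adjusted p = 0.0349 and 0.0407). The epithelial list also passed without ligand-treated replicate 5 (adjusted p = 0.0402). Of the blood and neuroendocrine markers, CD68 rose by 0.35 and CD14 fell, being at least 1.10-fold lower.

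The ligand contrast was set against the first contrast gene by gene. Of the 1746 genes changed on arrays labelled PPARD, 389 changed again with GW501516. In 320 of these (18.3% of 1746) the ligand moved the gene the opposite way: 202 had risen and then fell, and 118 had fallen and then rose. With the ligand 284 of the 320 lay closer to control than before and 36 farther from it. An opposite call means a move towards control, and a gene ends farther away only by passing control by more than its first change. The selection thus largely sets this count, which is no separate evidence of a return to control. The remaining 69 of the 389 moved further the same way, 49 up and 20 down. Independent lists of these sizes would share 78.2 opposite and 80.1 same-way calls. MSMP (2.95, then -2.00), LINC00261 (1.89, then -1.45), CXCL8 (1.68, then -1.21) and IFIT2 (1.28, then -1.01) were among those that had risen. TFF2, TFF3, CEACAM6 (-1.36, then 1.66), SLPI (-0.81, then 0.81) and PLIN2 were among those that had fallen. FCGBP fell in both (-0.74, then -1.31). PDK4, ANGPTL4 and PLIN2 passed the control level, ending 5.21, 4.23 and 2.15 above it. Of the 320, 219 were not called against control on ligand-treated arrays, 58 were called beyond control on the other side, and 43 still on the side of their first change. Adjusted over the 1746 genes alone, 402 were opposite and 85 the same way. These genes were selected with the PPARD-labelled arrays that the ligand contrast also uses, which tilts their signs towards opposite ones. No simulation was run for this adjustment, so the 402 have no figure to be set against.

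Both contrasts use the PPARD-labelled arrays, whose chance values push them in opposite directions. In 100 simulated data sets with the PPARD changes, and with the ligand changes given to random genes, 49 to 83 genes were called opposite (mean 65.0) and 34 to 71 the same way (mean 56.1). These data sets gave fewer calls than the arrays, on average 1475 and 816. Over all genes, which are not independent replicates, the 2 sets of fold changes had a covariance of -0.0201 against -0.00547 simulated with no effect, a difference of -0.0146. Their correlation was -0.316 against -0.500 simulated with no effect, weaker than with no effect. The groups are too small to be split into parts of 2 arrays, and part of the excess may come from the shared arrays. Without PPARD replicate 6, 246 genes changed again and 207 of them were opposite. Without PPARD replicate 4 or 5 the opposite calls were 224 and 242.

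**Figure D3:**
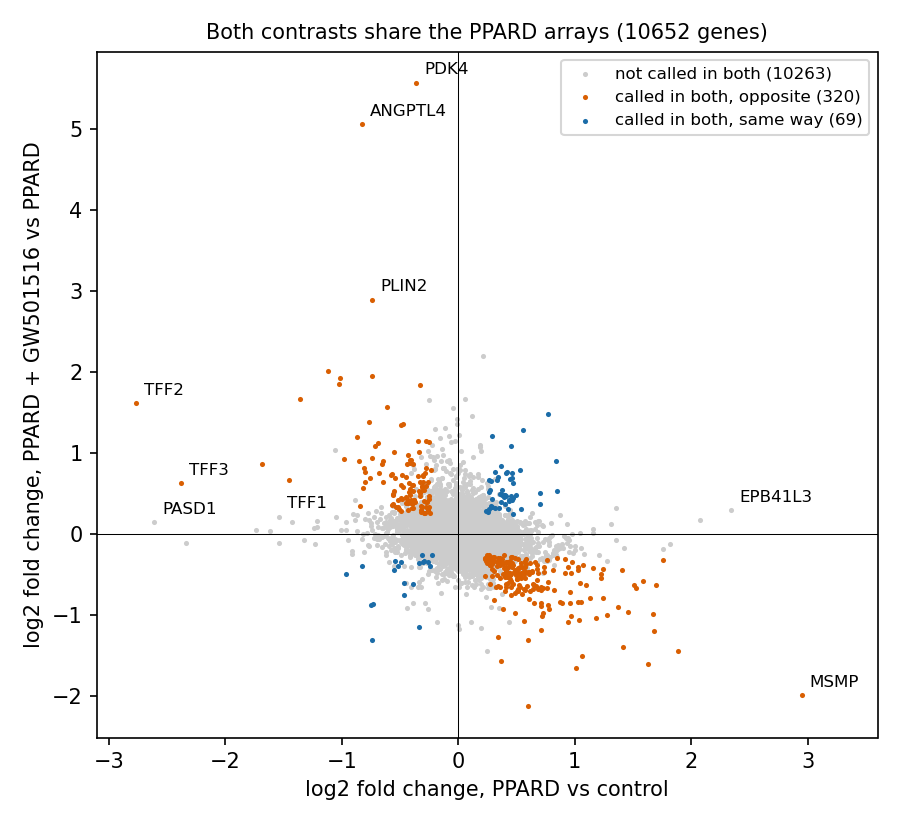
Log2 fold change on arrays labelled PPARD against control (x axis) and with GW501516 against PPARD (y axis) for the 10652 genes, 1 point per gene. Orange marks the 320 genes called in both with opposite signs, blue the 69 called in both the same way and grey all others; TFF2 lies at -2.77 and 1.61, and MSMP at 2.95 and -2.00.

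Against control, the PPAR targets PDK4 and ANGPTL4 had the largest rises on ligand-treated arrays. PDK4 was 5.21 ± 0.09 higher (37.0-fold), ANGPTL4 4.23 ± 0.10 (18.8-fold), EPB41L3 2.63 ± 0.10 and PLIN2 2.15 ± 0.07. LRRC31 was not above background on any control array and was at least 4.43-fold higher with the ligand. LXN and IGFBP2 each rose by 2.25, the integrin gene ITGB4 by 1.84, SHISA2 by 1.74 and TYRO3 by 1.71. PASD1 (-2.47 ± 0.07) and FCGBP (-2.05 ± 0.08) fell, and TUB and KLK6 were at least 3.81-fold and 2.71-fold lower, being below background on all ligand-treated arrays. MAGEA10, MYLIP, ABCG1, CCL26 and MMP13 fell by 1.66, 1.63, 1.60, 1.58 and 1.54, with MMP13 detected on 1 of 3 ligand-treated arrays. MYLIP encodes a ubiquitin ligase for the low density lipoprotein receptor and ABCG1 a sterol exporter. In all, 2447 genes (23.0%) changed, 1316 up and 1131 down, with 58 rises and 40 falls of 2-fold or more.

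PPAR target genes had 18 rises and 0 falls among 21 in this contrast (19 and 0 adjusted over the list alone; adjusted p = 9.45e-19, and adjusted p = 0.00333 with an estimated correlation), with ACAA2 up by 1.51. Cholesterol synthesis genes had 11 rises and 0 falls among 19 (16 and 0 adjusted over the list alone), with TM7SF2, INSIG1, FDPS and HMGCS1 up by 0.85, 0.77, 0.66 and 0.65. Hypoxia and glycolysis genes had 16 rises and 0 falls among 33, also adjusted over the list alone, with ADM, NDRG1, ENO2 and INSIG2 up by 1.00, 0.92, 0.85 and 0.77. Both lists had an adjusted p of 4.10e-08. With an estimated correlation the cholesterol list had an adjusted p of 0.0101 and the hypoxia list an adjusted p of 0.0216.

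Interferon response genes were still higher than control with the ligand, with 15 rises and 2 falls among 33 (16 and 2 adjusted over the list alone). IFI44L, IFI27, IFI44 and DDX60 rose by 1.67, 1.25, 1.07 and 1.06, and BST2 and PSMB8 fell. The adjusted p was 6.41e-06, and adjusted p = 0.288 with an estimated correlation. Proliferation genes had 12 falls and 2 rises among 44 (14 and 2 adjusted over the list alone), with MCM4 at -0.58 ± 0.12, BIRC5 at -0.49 ± 0.07 and CDT1 at -0.48 ± 0.08, while CENPA and BUB1 rose. Their adjusted p was 7.11e-04, and adjusted p = 0.108 with an estimated correlation. Epithelial genes had 6 rises and 1 fall among 17 (7 and 1 adjusted over the list alone), with ITGB4, JUP, LAMB3 and EPCAM up by 1.84, 0.74, 0.73 and 0.61 (adjusted p = 0.00570, and adjusted p = 0.108 with an estimated correlation). Mesenchymal and TGF-beta genes had 9 rises and 2 falls among 27, the same counts adjusted over the list alone, with COL1A2, THBS1 and COL6A3 up by 1.69, 1.41 and 1.35. For that list the adjusted p was 0.0173, and adjusted p = 0.180 with an estimated correlation.

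The remaining lists did not pass against control. NRF2 and metallothionein genes had 7 rises and 3 falls among 22 (adjusted p = 0.0550), with ABCC3 at 1.50 and AKR1C2 at 1.20. Fatty acid synthesis genes had 6 and 1 among 18 (0.0591), with ACSS2 at 0.67, and fatty acid oxidation genes 7 and 1 among 29 (0.0679), with HADHB at 0.59 and ACSL4 at 0.34, whose other probe gave -0.13. Nuclear receptors and coregulators had 1 rise and 7 falls among 21 (0.112), including the vitamin D receptor gene VDR at -0.58 and NRIP1 at -0.47. NF-kB targets had 5 and 2 among 15 (0.117), mucosal secretory genes 5 and 2 among 14 (0.132) and oxidative phosphorylation genes 1 and 4 among 43 (0.194), where SDHC gave -0.36 and its other probe 0.04. Androgen receptor and luminal prostate markers had 3 and 5 among 10 (0.877), with SLC45A3 at 0.75 and HOXB13 at -0.58. ATF4 and unfolded protein response genes had 3 and 5 among 39 (0.911), with GDF15 at 0.87. The NRF2 list passed as higher under all 3 other value scales (adjusted p = 0.0437 to 0.0484) and without control replicate 4, control replicate 5 or ligand-treated replicate 5 (adjusted p = 0.0411, 0.0330 and 0.0358). The fatty acid synthesis list passed without background correction and with the authors' processed values (adjusted p = 0.0338 and 0.0356), and without ligand-treated replicate 5 or control replicate 6 (adjusted p = 0.0499 and 0.0454). The fatty acid oxidation list passed without ligand-treated replicate 6 (adjusted p = 0.0484). CD14 fell among the blood and neuroendocrine markers, being at least 1.11-fold lower.

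The PPARD and ligand-treated arrays, each against control, were compared for genes in common. Of the 1746 genes changed on arrays labelled PPARD, 1021 (58.5%) changed the same way on ligand-treated arrays, 594 up and 427 down, and 58 changed the opposite way. Independent lists of these sizes would share 126 rises and 76.8 falls, and 100 simulations of unchanged groups against the same control arrays shared 0, since unchanged groups give almost no calls. In 100 simulations with both sets of changes, the second given to random genes, 126 to 181 were shared the same way (mean 159) and 102 to 165 the opposite way (mean 132). These gave on average 1475 and 2013 calls. EPB41L3, IGFBP2, COL1A2, PASD1, TUB, MAGEA10 and the trefoil factors were among the shared genes. Over all genes the fold changes correlated at 0.616 against 0.499 simulated with no effect, with a covariance of 0.0472 against 0.00545 and a difference of 0.0417. These simulations held the shared control arrays too, and gave somewhat more same-way than opposite calls. Both groups are labelled as overexpressing PPARD, so more shared calls than with random genes would follow from the design alone. The excess is therefore no separate evidence. The 3 control arrays cannot be split into parts of 2, and part of the excess of shared calls may come from them.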

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

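The other value scales and the leaving out of single arrays were planned as alternatives, but their use as tests of an explanation was chosen after the results they bear on had been seen, as were the tests of the arrays not shared by both contrasts for the opposite calls and of the PPARD probe.

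Signal also appeared in probes that the comparisons above do not use. Of 3313 detected probes without a gene name here, 268 changed on arrays labelled PPARD against control, 155 with GW501516 against PPARD and 490 with GW501516 against control.

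Each contrast of 3 arrays with 3 allows 10 splits, too few for a share under 0.05. The real split gave 1746 genes for PPARD against control, 966 for ligand-treated against PPARD and 2447 for ligand-treated against control, and the highest of the other splits gave 0 in each. In each contrast 1 of the 10 splits, the real one, gave as many. Every other split mixes arrays of the 2 groups compared, so real differences add to the spread and count against a call. The 0 calls there are therefore no measure of what unchanged groups would give.

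PPAR target genes fell on arrays labelled PPARD with no ligand added (median log2 fold change -0.21). The choice of background correction or normalization is argued against, since the list fell under all 3 other value scales with an adjusted p of at most 0.00138. The brightness of the list's genes is argued against too, since its median lay at percentile 0 of 10000 random lists matched on signal. A candidate explanation is that the unliganded receptor holds ligand-responsive genes down. It takes a raised receptor from the label alone, since the PPARD probe tested gave -0.31 on these arrays (adjusted p from limma = 0.0649). The values do not show that the receptor was raised. The 200 genes outside the list that rose most with the ligand had a median PPARD effect of -0.08, -0.11 and -0.13. These are the 3 ways of using separate PPARD arrays for each contrast (1 for the ligand effect), each at percentile 0 of matched sets. This cannot decide the question, since the effects from separate arrays had a negative covariance over all genes (-0.0128 at its highest). The strongest risers with the ligand would therefore lie low on arrays labelled PPARD whatever the cause. The strongest fallers were not tested, and more called genes rose and then fell (202) than the reverse (118). A difference in culture shared by all 3 arrays labelled PPARD would give the same fall of the list. It stays open, as do the unliganded receptor and the result of camera with an estimated correlation (adjusted p = 0.0808).

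For 320 genes changed on arrays labelled PPARD the ligand moved expression the opposite way. The PPARD arrays shared by both contrasts are argued against as the whole cause, since the covariance of the effects from arrays not shared was -0.0128 at its highest over 3 assignments. A single deviating PPARD array is argued against as well: without any one of them 207 to 242 opposite calls were made, against 33.1 to 40.4 for independent lists in the same fits. With each ligand effect set against 1 PPARD array and the PPARD effect taken from the others, at least 60.4% of the called genes outside the PPAR target list had a ligand effect of opposite sign, which restates the pattern and explains nothing. A ligand that counteracts part of the PPARD changes cannot be told apart from a deviation common to all 3 arrays labelled PPARD, which the design ties to the group.

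The PPARD probe tested did not rise on the arrays labelled PPARD, and a second, dimmer one was detected on 0 of them. A single mislabelled array is argued against, since 9 of 9 arrays correlated best with an array of their own group. An exchange of whole groups would leave these correlations unchanged, so they say nothing about it, and it was not tested. A probe outside the introduced sequence may account for the value of -0.31. This cannot be told apart from a construct that was not expressed, because neither the probe sequences nor the vector sequence were used here. A rise of known PPAR target genes with GW501516 does not settle this, since no control cells received the ligand.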

How the results depend on the processing

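Outside the array left out and the estimated correlation, all 49 counts of changed, shared or opposite genes and of called lists stayed between 0.88 and 1.33 times the reported ones. With an estimated correlation 5 of the 18 called list tests passed. Adjusted p from camera also rose where the estimate lay below the preset 0.01. With the ligand against PPARD, cholesterol synthesis genes (estimate -0.0454) went from 1.16e-07 to 0.0101. Fatty acid oxidation genes (0.00585) went from 0.0316 to 0.154. A higher correlation between genes is therefore not the whole reason. With an estimated correlation camera also takes its p-values from the 6 residual degrees of freedom, and with a preset one from nearly as many as there are genes. A call lost under the estimate is thus no test of the correlation alone, and the share of each part was not tested. Leaving out 1 array, which also leaves fewer samples, gave 1128 to 1787 genes for PPARD against control, 635 to 918 for ligand-treated against PPARD and 1759 to 2376 for ligand-treated against control. It gave 685 to 931 shared genes, 246 to 356 genes changed again with the ligand, 207 to 291 opposite calls and 16 to 21 lists. The lowest counts of 1128, 635, 246 and 207 came without PPARD replicate 6, each over 1.5 times below the reported count. Counts also fell without PPARD replicate 4 or 5, to 1177 and 1171 genes for PPARD against control. For ligand-treated against PPARD they were 698 and 745, and the opposite calls 224 and 242.

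Of 4503 alternative values for 261 named results, 4181 kept direction and call, 263 lost the call, 52 gained it and 7 reversed. All 7 reversals came from another probe of the gene, and the cause was not tested: CPT1A gave 0.0252 and 0.0694 for PPARD against control and -0.0887 with the ligand, IFI44L -0.00291 for PPARD against control, ATP5MC1 0.0557 with the ligand, and ACSL4 -0.127 and SDHC 0.0352 for ligand-treated against control. Over the 3 other value scales, 14 of 144 list tests gained a call and 0 lost one: NRF2 genes in both contrasts with the ligand under all 3, and under 2 of them cholesterol synthesis genes for PPARD against control, oxidative phosphorylation and epithelial genes with the ligand, and fatty acid synthesis genes for ligand-treated against control. These 2 are the scale without background correction and the authors' processed values. Both are quantile-normalized without that correction, so their gains are not separate evidence.

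Same-numbered arrays are not known to be pairs. Their residual correlations ranged from -0.00758 to 0.242 over 9 pairs, and 4 exceeded 0.1. Arrays of different groups and numbers had a median of -0.0506. Since residuals are taken from the group mean, this value follows in part from the same-number ones and is no separate baseline. Pairing stays possible, and the main fit does not model it. Arrays correlated best with their own number in 6 of 9 cases. With the replicate block the counts were 1801, 1012 and 2605 in the 3 contrasts, 255 of 261 named results kept their call and all 48 list tests did. With the block PPARD passed with the ligand (0.35, adjusted p = 0.0491) and CD14 did not (adjusted p = 0.0590), while for PPARD against control PPARGC1B and NDUFV1 gained a call and BCL3 and FKBP5 lost one. A slide block was not run, since neither labels nor files name slides, and the alternative without a detection filter covers only named probes, which were detected on at least 1 array. Signal over background limits genes detected on few arrays.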

Other observations

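All tests in this part were chosen after the values that prompted them had been seen, and the genes of the lists named here were chosen then too.

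Genes near the trefoil cluster on chromosome 21 were looked at with the gene order of GRCh38.p14, where TFF3, TFF2 and TFF1 lie side by side. Of the 5 protein-coding genes on each side 3 were measured, all on the TFF3 side. ABCG1, the nearest of them, fell by 0.73 ± 0.11 on arrays labelled PPARD (adjusted p = 9.94e-04), and C2CD2 and ZBTB21 gave -0.16 (adjusted p = 0.183) and 0.09 (adjusted p = 0.502). ABCG1 fell further with the ligand (-0.87, adjusted p = 2.84e-04), where TFF2 and TFF3 rose and C2CD2 rose by 0.65. A change along the chromosome around the trefoil cluster is a hypothesis that these 3 genes leave open: 1 of them fell, and no gene on the TFF1 side was measured.

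Sterol genes moved in different ways with the ligand. Cholesterol synthesis genes rose, while MYLIP and ABCG1, known targets of the oxysterol receptor LXR, fell by 0.88 and 0.87 against PPARD. ABCA1, a target of both LXR and PPAR receptors, rose by 0.41. Lower LXR activity could produce such falls, and the values leave it open. On ligand-treated against control arrays 8 further LXR targets had a median of -0.10, at percentile 12.7 of 10000 lists matched on signal. On arrays labelled PPARD against control, where MYLIP and ABCG1 fell by 0.75 and 0.73, their median was -0.21, at percentile 0.27, and with the ligand against PPARD it was 0.07, at percentile 93.2. Of these 8, LPCAT3 fell by 0.68 on arrays labelled PPARD and rose by 0.75 with the ligand, and RGS16 fell by 0.65 in the first of these contrasts. On ligand-treated against control arrays RGS16 fell by 0.59 while NPC1 rose by 0.37. SREBF1 and NR1H3, also known LXR targets, gave -0.01 and -0.13 with the ligand against PPARD.

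Some cancer-testis genes, silent in most adult tissues, were among the largest falls on arrays labelled PPARD. Of 16 measured, chosen by symbol, 4 fell and 1 rose, which is 31.2% against 16.4% of other genes (Fisher's exact test, two-sided, p = 0.164). PASD1, MAGEA10 and MAGEA1 fell by 2.61, 1.54 and 0.97, and MAGEA12 rose by 0.60. With the ligand 0 fell and 1 rose, and PASD1 gave 0.15 and MAGEA10 -0.12. On ligand-treated against control arrays 3 fell and 1 rose, which is 25% against 23.0% of other genes (Fisher's exact test, two-sided, p = 0.772). Outgrowth of other subclones during derivation of the PPARD cells may produce such a pattern, and with 16 genes these tests neither bear this out nor exclude it. GAGE genes are close copies whose probes may not separate them.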
